A study of Homo sapiens with 2 samples.

How the data were processed

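The series holds 2 samples of the human embryonic stem cell line H9, ESCs and the ffEPSCs derived from them, each deposited as a table of gene counts and a table of repeat counts with 1 column per cell. Groups were taken from the cell type in the labels. Per the labels' protocols, libraries were made with Smart-seq2. An RNA extraction kit for bulk material is named as well, and how it was used on single cells is not given in the sources used here. The values are whole-number counts, deposited by the authors without normalization. The submitters' processing notes name bcl2fastq, HISAT2 2.2.1, SAMtools 1.6, featureCounts and Subread 2.0.6, and the builds GRCh38 and CHM13 (telomere to telomere), without saying which build served which table. The annotation, the repeat library, the handling of reads that map to many places and the use of strand are not given in the sources used here. Repeats are the rows most exposed to this, since reads of young copies map to many places.

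The gene tables list 22474 genes, each with reads in at least 3 of the 41 cells, and 0 mitochondrially encoded genes. In each cell about 98% of non-zero gene counts were even (median 98.5% in ESCs and 98.4% in ffEPSCs), as when both reads of a pair are counted, so counting intervals are narrower than the number of fragments would give. No pair of cells had identical counts, and the highest Pearson r between cells was 0.878. The repeat tables give names without classes, so names were sorted by name alone into simple repeats, RNA genes, composites, and transposable elements and satellites. Shares of repeat counts were computed for these 4 kinds, but not per class, such as LINE or LTR. Doublets were not called. Cells were not clustered.

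Cells had to have at least 100000 gene counts, 2000 genes and at most 25% mitochondrial counts, and 0 cells were removed. Counts were summed over the cells of a library and divided by the library's total (CPM), or by total repeat counts for repeats. Ratios are log2 of ffEPSC over ESC after adding 1. With 1 sample per state and cells not being replicates, no p-value or standard error was computed. Intervals are exact Poisson for levels, exact conditional binomial for ratios and Clopper-Pearson for shares, all at 95% and for counting error only. A count of 0 allows up to 3 counts, which is 0.0113 CPM in the ESC library and 0.00802 CPM in the ffEPSC library.

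The 32 gene lists and 8 repeat lists, the rules for naming genes and the alternative settings, except those named below as added, were fixed before the data were examined. Results of 1 of the gene lists are not reported. List members were measured if they had 5 CPM in at least 1 library (100 CPM of repeat counts for repeats), and each list's median ratio was placed among 10000 random lists of the same size drawn from 20 bins of mean expression. Named genes were the 12 largest and 12 smallest ratios among genes with 20 CPM in the higher library, reads in at least 50% of its cells and a ratio of cell means of at least 2-fold in the same direction, leaving out ribosomal protein genes, pseudogenes and rows without a symbol. Added to them were up to 4 members per list and 12 genes named in any case. For repeats they were the 8 largest and 8 smallest ratios among transposable elements and satellites with 100 repeat CPM and the same direction in the mean of cells, plus 12 repeats named in any case. Further list members were named after their values were seen: LEFTY1, DPPA2, DPPA5, OTX2, SPARC, ZNRF3, ID1, ID3, IFITM2, LAMA5 and HERV17-int. Coordinates and gene types come from GENCODE version 29 on GRCh38, which matched 21291 of the listed genes, and are not taken from the deposited tables.

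Detection and correlations between cells used counts thinned to 13000000 per cell. Genes were grouped by autosome with the same annotation. The per-cell shift of a chromosome is the mean over its genes with 20 CPM over all cells of log2(CPM + 1) minus the mean of the ESC cells (of the other ESC cells for an ESC cell), minus the cell's median autosome. A chromosome was picked at a median ratio of 0.25 or more, and cells were separated at a mean shift of 0.3. The 5 ffEPSC cells called cells with little or no shift lay below 0.3 both in that mean and on chromosome 5.

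The steps were tested on simulated data for this comparison, with cells drawn at the real depths with the spread between ESC cells and 200 of 22474 genes changed. Genes changed 2-fold, 4-fold and 8-fold upward came back with median log2 ratios of 1.04, 1.90 and 2.90, and 100% of each had the right direction. Unchanged genes had 5th and 95th percentiles of -0.61 and 0.57. Of 100 unchanged lists of 20 genes, 7% lay outside the central 95% of random lists. Simulated genes varied independently of each other, and both groups had the ESC spread. That rate thus need not hold for real lists, whose members can vary together. Changed genes were drawn only from those with 20 CPM or more, so genes between the floor of 5 CPM and that level were not tested. Alternatives were the mean of cells, TMM factors (edgeR), a pseudocount of 0.1, other floors, other cell filters, other totals for repeats, thinning depths and, added after the data were seen, single sets, cells left out in turn, genes of 5 chromosomes left out, ffEPSC cells with little or no chromosome shift, and ESC cells with POU5F1 below 300 CPM left out. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16.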

Results

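Single H9 cells in 2 states were profiled with Smart-seq2, a full-length protocol that copies polyadenylated RNA from a single cell and amplifies it without molecular barcodes. H9 is an established human embryonic stem cell (ESC) line. The other state was feeder-free extended pluripotent stem cells (ffEPSCs), obtained by converting H9 ESCs, and the question was how gene expression differs between the states. The ESC library held 16 cells with 265412149 gene counts, from 11714517 to 19965639 per cell, and the ffEPSC library held 25 cells with 374101290 gene counts, from 12507469 to 17811209 per cell. A further table per library gave counts for 5833 repeat names, with 129041480 counts in the ESC library and 179248893 in the ffEPSC library. Each state was 1 deposited sample, so no test between the states was possible, and the values below describe these libraries. Levels are summed counts scaled to the library's total gene counts (CPM), or to its total repeat counts for repeats (repeat CPM). Ratios are ffEPSC over ESC, on the log2 scale after adding 1 CPM, and 95% intervals cover counting error only, since reads of amplified cDNA are not independent molecules. Cell names carried a set number from 1 to 4 whose meaning was not given. ESC cells came from sets 1 (7 cells) and 3 (9 cells), and ffEPSC cells from sets 1 (3 cells), 2 (9), 3 (2) and 4 (11), so only sets 1 and 3 hold cells of both states, and ratios within them rest on 3 and 2 ffEPSC cells.

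The libraries shared most of their expression pattern. Over 10825 genes with 5 CPM or more in at least 1 library, log2 levels had a Pearson r of 0.909 and a Spearman rho of 0.917 across genes, which are not independent replicates. Log2 ratios had a median of 0.04, with 5% of genes below -1.10 and 5% above 1.31. For scale, the ratio of set 3 to set 1 among ESC cells alone had 5th and 95th percentiles of -0.84 and 0.97, and the ratio of set 4 to set 2 among ffEPSC cells alone had -0.81 and 0.77. Within set 1 the ffEPSC over ESC ratio ran from -1.80 to 1.74 between the same percentiles, and within set 3 from -2.24 to 1.46. Across genes the ratio within set 1 correlated with that within set 3 at r = 0.397.

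Core pluripotency genes were read in both libraries, genes of the naive state were higher in the ffEPSC library, and genes of the primed state were lower as a group. POU5F1, the OCT4 gene, stood at 892 CPM in ESCs and 1061 CPM in ffEPSCs (log2 ratio 0.25), NANOG at 132 and 175 CPM (0.40), SOX2 at 33.9 and 44.9 CPM (0.39), and the de novo methyltransferase gene DNMT3B at 427 and 586 CPM (0.46). ZFP42, known as REX1, was at 186 and 138 CPM (-0.43). In 4 of the 16 ESC cells POU5F1 was at 63.5 to 218 CPM, against 496 CPM or more in the other 12. NANOG was at 29.3 to 68.9 CPM in the 4 cells, which overlapped the other 12 (66.5 to 193 CPM). These 4 cells were also the shallowest, with 11714517 to 14683949 gene counts against 16349317 to 19965639. A median of 11964 genes had a read in them, against 13318. Whether they differ in state or in library quality was not tested. Without these 4 cells, a split chosen after the data were seen, the log2 ratio was -0.02 for POU5F1, 0.21 for NANOG and 0.28 for SOX2. Among 22 measured core pluripotency genes, 6 were at least 2-fold higher in the ffEPSC library, 0 were at least 2-fold lower, and the median log2 ratio was 0.40, above 99.97% of 10000 random lists matched on expression. Within sets 1 and 3 the median was 0.60 and 0.49, and without the 4 ESC cells low in POU5F1 it was 0.24. The higher members were the TGF-beta family ligand gene NODAL (13.96 CPM in ESCs and 180.1 in ffEPSCs, log2 ratio 3.60), the NODAL antagonists LEFTY2 (3.59) and LEFTY1 (2.204), GDF3 (2.68), UTF1 (2.32) and DPPA2 (2.24). DPPA2 was higher within set 1 (2.196) and lower within set 3 (-0.45).

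Of 26 genes of the naive pluripotency list, 18 were listed and 11 reached 5 CPM in at least 1 library. All 11 were at least 2-fold higher in the ffEPSC library. A gene nearly unread in ESCs can pass that floor only through ffEPSCs, so the floor favours this outcome. The median log2 ratio of the 11 was 2.61, above 100% of the matched random lists, but 1.76 with no floor and 4.69 at a floor of 20 CPM. It was 3.45 within set 1 and 2.25 within set 3, against 0.02 between the ESC sets. DNMT3L, the catalytically inactive cofactor of the de novo methyltransferases, differed most: 0.219 CPM (95% interval 0.166 to 0.282) in ESCs and 261 CPM in ffEPSCs, a log2 ratio of 7.75, with each of the 25 ffEPSC cells above all 16 ESC cells. FGF4, a fibroblast growth factor of the early epiblast, was at 0.0377 and 25.7 CPM and TFAP2C, a transcription factor of naive cells and trophoblast, at 7.75 and 85.7 CPM. KLF4 had a log2 ratio of 2.61, DPPA3 of 2.34, and TFCP2L1 of 1.49. KLF4 reached 1 CPM in 4 of 16 ESC cells and 21 of 25 ffEPSC cells, and DPPA3 in 6 and 19. NLRP7 (3.84) and ALPG (3.79) rested on few cells, with 1 CPM or more in 7 and 8 ffEPSC cells, and ALPG had no reads in either state's set 3. DPPA5 was higher over all cells (1.28) and lower within sets 1 (-1.54) and 3 (-1.42). KLF17 was not listed in the table, which names no gene with reads in fewer than 3 cells, and is not analysed here.

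Genes marking primed pluripotency were lower as a group in the ffEPSC library. Of 21 measured members, 7 were at least 2-fold lower and 1 at least 2-fold higher, with a median log2 ratio of -0.78, below all 10000 matched random lists. The median was -0.27 within set 1 and -0.76 within set 3. CYTL1, a cytokine-like gene, was at 12.99 and 0.0107 CPM (-3.79), the ERK phosphatase gene DUSP6 was at 118 and 15.5 CPM (-2.85), the WNT receptor gene FZD7 at 72.1 and 12.6 CPM (-2.42), and VIM, which encodes vimentin, at 37.1 and 12.2 CPM (-1.53). OTX2, a transcription factor of primed epiblast, was at 156 and 56.7 CPM (-1.44), but at -0.27 within set 1 and -0.18 within set 3. ETV5 was the member at least 2-fold higher (1.45). Among 9 measured long non-coding RNAs of pluripotent cells, LINC01108 was higher (2.72) and LINC00458 (-2.14) and LNCPRESS2 (-1.096) lower. LINC01356 was higher over all cells (1.01) but at -0.60 within set 1. The list's median was -0.32, at the 3.12 percentile of random lists, but 0.19 at a floor of 20 CPM, with no floor or without genes of the 5 chromosomes described below, 0.14 without the 4 ESC cells low in POU5F1 and -0.07 within set 1, so it had no stable direction.

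**Figure D1:**
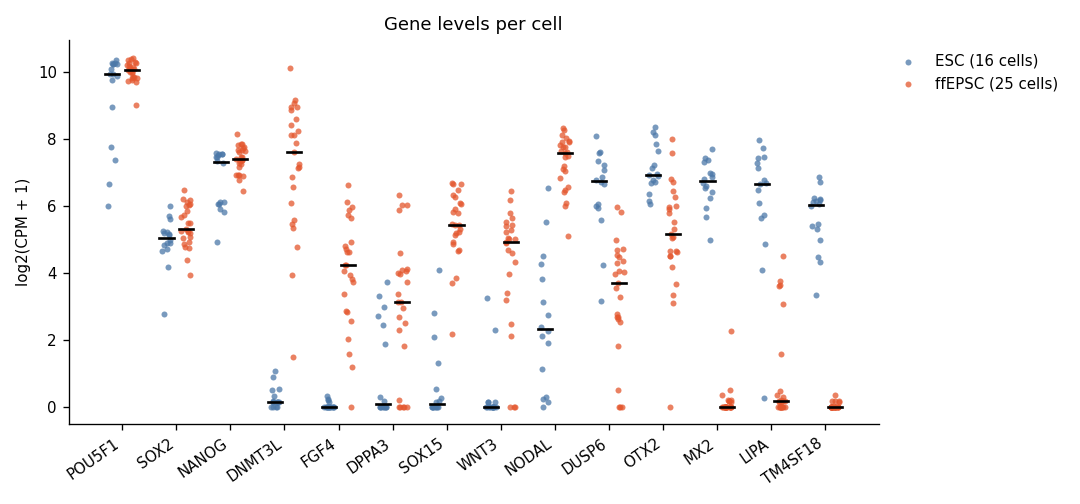
Levels per cell, as log2(CPM + 1), of 14 genes in 16 ESC cells (blue) and 25 ffEPSC cells (orange), with black bars at the median over cells. POU5F1, SOX2 and NANOG overlap between the states, DNMT3L lies higher in each of the 25 ffEPSC cells than in any ESC cell, and MX2 and TM4SF18 lie lower in each of them.

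Markers of the 8-cell stage and of other lineages were mostly unlisted or low in both libraries. Of 30 genes of the 8-cell list, 4 were listed, and ZSCAN4 was not among them. Their median log2 ratio was 1.39, carried by DPPA3 and CCNA1 (2.05 over all cells, 0.00 within set 1 and -1.43 within set 3), and it was 0.43 within set 1, -0.50 within set 3 and 0.72 at a floor of 20 CPM. GATA3 had 0 reads in the ESC library, which allows up to 0.0113 CPM, and 0.695 CPM in the ffEPSC library from 3 of 25 cells. GATA6 was not listed. TBXT, the brachyury gene, was at 0.249 and 2.41 CPM, with a log2 ratio of 1.45 over all cells, -0.64 within set 1 and -0.02 within set 3, and PAX6 was at 0.354 and 0.0802 CPM. Of 5 measured trophoblast genes, KRT8 (578 and 1570 CPM, 1.44) and TFAP2C were at least 2-fold higher and KRT7 lower (-1.595, but 1.19 within set 1). The list's median was 0.89, but 0.32 within set 3, 0.23 without genes of the 5 chromosomes described below and 0.055 in the 5 ffEPSC cells with little or no shift on them. The 2 measured amnion genes had a median of 0.31, which was -0.31 within set 1 and -2.66 within set 3. Of 8 primitive endoderm genes FN1 was higher (1.08) and FRZB lower (-2.47), with a median of 0.67 that was 0.91 within set 1, 0.26 within set 3 and 0.13 with no CPM floor.

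In the mesoderm and definitive endoderm list, 4 genes were measured and the ligand genes WNT3 (0.799 and 29.2 CPM, 4.07) and BMP4 (4.39 and 43.8 CPM, 3.05) were higher while SNAI2 was lower (-2.51). The list's median of 1.32 rested on these few genes and was 0.30 within set 3, 0.53 in these 5 ffEPSC cells and -0.42 without genes of chromosomes 5, 11, 14, 20 and 22 (described below), where BMP4 lies. Of 4 neuroectoderm genes, FABP7, a brain fatty acid binding protein gene, was at 62.6 CPM in ESCs and 1.03 CPM in ffEPSCs (-4.97), and the neuronal microtubule gene MAP2 was at 9.87 CPM in ESCs (-3.42). Their median was -1.84, -1.93 within set 1 and -1.88 within set 3, but -0.30 with no CPM floor, and lower with a pseudocount of 0.1. Of 6 fibroblast or feeder genes, 4 were at least 2-fold lower in the ffEPSC library, with a median of -1.37 that was -2.35 within set 1, -1.91 within set 3, -0.65 with no CPM floor and -0.99 in the 5 ffEPSC cells with little or no shift on the 5 chromosomes. S100A4 was at 34.2 and 0.460 CPM, TAGLN at 47.1 and 12.5 CPM, and SPARC was the exception (1.17 over all cells, -0.54 within set 3).

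Signalling genes differed most for WNT and for NODAL and BMP. Of 20 WNT targets, 13 were listed and 5 reached the CPM floor, which can be passed through the ffEPSC library alone. All 5 were at least 2-fold higher in the ffEPSC library. Their median log2 ratio was 2.09 (2.72 within set 1, 1.66 within set 3, 1.56 with no CPM floor), above 99.97% of random lists. Besides WNT3 these were the transcription factor gene TCF7 (1.1 and 19.3 CPM, 3.27), the feedback gene AXIN2 (2.09), the receptor gene FZD5 (1.86) and ZNRF3, whose log2 ratio of 1.298 was -1.07 within set 1. Of 16 genes of the TGF-beta, NODAL and BMP pathway, 8 were at least 2-fold higher and 1 lower. NODAL, LEFTY1, LEFTY2 and GDF3 among them are also in the core list. ID1, a BMP target, was at 175 and 791 CPM (2.17) while ID3 was lower (-1.03). The median was 1.09 over all cells, 0.71 within set 1, 0.18 within set 3, 0.68 with no CPM floor and 0.69 in the 5 ffEPSC cells with little or no shift on the 5 chromosomes. FGF and ERK targets had no common direction (median 0.04 over 15 genes, 0.36 within set 1 and -0.04 within set 3): the cyclin gene CCND1 was at 57.3 and 303 CPM (2.38) and DUSP4 at 2.44 (-0.37 within set 3), opposite to DUSP6. Of 10 LIF and STAT3 targets, 4 were at least 2-fold higher, with a median of 0.69 that was 0.41 within set 1 and 0.13 within set 3. PIM1 (1.37) and IL6ST (1.297) were among them and both were lower within set 3 (-0.39 and -3.14). IL6ST was at -0.12 within set 1 as well, and PIM1 at -0.043 in the 5 ffEPSC cells with little or no shift.

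Stress and metabolic groups showed smaller shifts. Each of 19 measured genes of the integrated stress response, the program under ATF4, was higher in the ffEPSC library, with a median of 0.61 (0.68 within set 1, 0.41 within set 3) and 4 at least 2-fold higher, among them STC2 (1.69) and the amino acid transporter gene SLC7A5 (1.47). The median between the ESC sets was 0.27. Of 24 cholesterol synthesis genes 20 were lower and 3 at least 2-fold lower, with a median of -0.60, below all 10000 random lists, and -0.77 and -0.52 within sets 1 and 3. SC5D, a late enzyme of the pathway, was at 427 and 200.3 CPM, and MVD at 106 and 51.3 CPM. Nuclear-encoded genes of oxidative phosphorylation had a median of 0.30, with 35 of 41 higher, but 0.13 and 0.16 within sets 1 and 3. NDUFV1, of respiratory complex I, was at 166 and 579 CPM (1.80) and SDHD at 351 and 777 CPM (1.15). Both lie on chromosome 11, whose genes were higher as a whole (described below). Glycolysis genes had a median of -0.01, with PFKL higher (1.07) and ALDOC lower (-1.13). The mitochondrially encoded genes were not listed and are not analysed here.

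Interferon-stimulated genes had no common direction, with 5 of 15 measured genes higher and 10 lower. IFITM1 (203 and 1337 CPM, 2.71), IFITM3 (409 and 2150 CPM, 2.39), BST2 (1.52) and IFITM2 (1.06), which restrict virus entry or release, were at least 2-fold higher. Of the measured genes 1 was at least 2-fold lower, and the list's median was -0.16. The IFITM genes are near-identical copies, and how the counting split reads between them was not given. S-phase genes had a median of -0.23 over 40 genes but -0.01 and 0.04 within sets 1 and 3, with CCNE2 lower (-1.70), and G2 and M genes had a median of -0.06 with CENPA higher (1.85). Genes of DNA methylation and heterochromatin had a median of -0.12, but 0.18 and 0.33 within sets 1 and 3, with DNMT3L and MORC2 (1.16, but -0.20 within set 1) higher and TET2 lower (-1.44). All 16 Polycomb genes stayed within 2-fold (median -0.14, but -0.47 within set 3), as did all 76 ribosomal protein genes (-0.10). Medians were 0.04 for 15 immediate early and heat shock genes (0.33 and -0.23 within sets 1 and 3), with FOS (1.38) and JUN (1.23, but -0.27 within set 3) higher, and 0.07 for 13 p53 targets (-0.08 and -0.34 within sets 1 and 3), with PLK2 higher (1.48) and TNFRSF10B lower (-1.50). The median was 0.07 for 19 epithelial and mesenchymal genes (-0.05 and -0.27 within sets 1 and 3), of which 2, LAMA5 and FN1, were at least 2-fold higher and 6 at least 2-fold lower, among them CLDN4 (-3.48) and CDH2 (-1.98). Of 11 imprinted genes PHLDA2 (1.62), KCNQ1OT1 (1.599) and ZNF597 (1.08, but -0.22 within set 1 and -0.46 within set 3) were at least 2-fold higher. The list's median of 0.23 was 0.06 within set 1, 0.14 within set 3 and -0.18 without genes of the 5 chromosomes, where PHLDA2 and KCNQ1OT1 lie. In the germ cell list only TDRD12 was measured (1.57), and the list's median was 0.82 with no CPM floor.

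**Figure D2:**
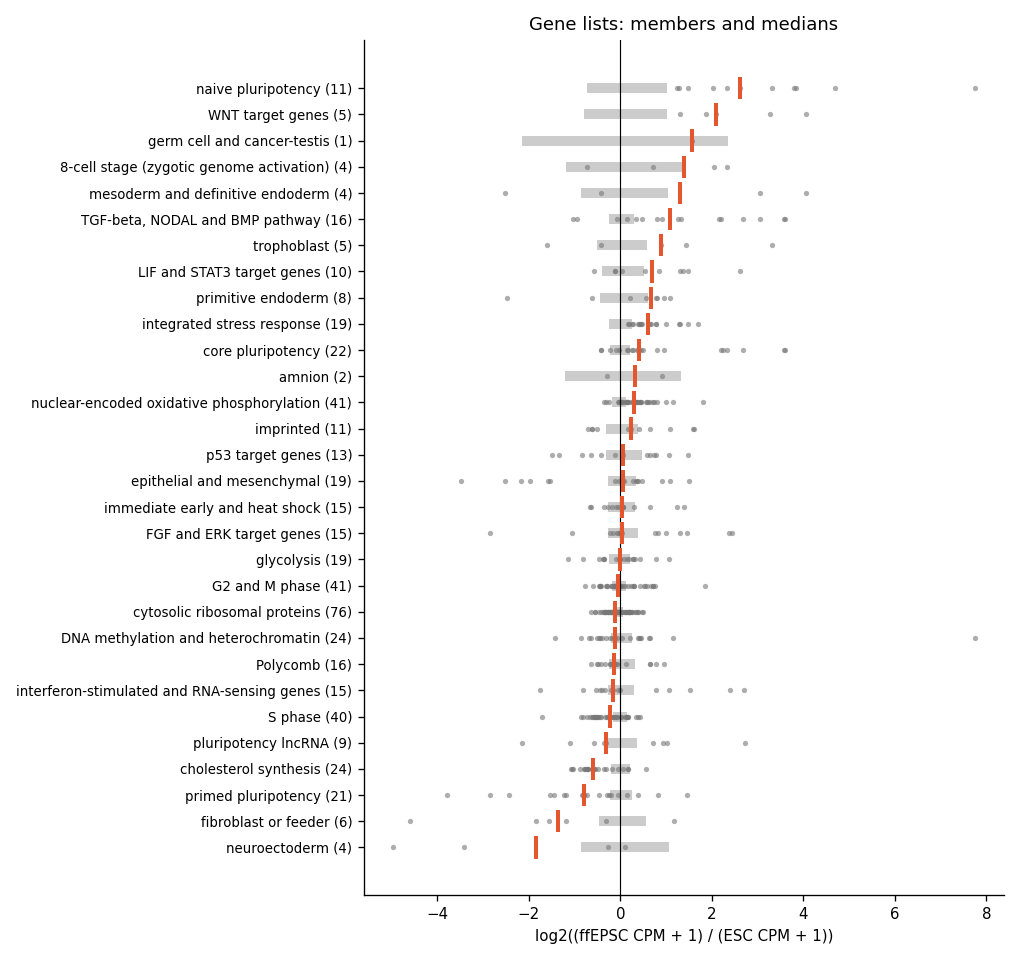
Log2 ratio of the ffEPSC over the ESC library for measured members (grey points) of each gene list reported, with the number of members in brackets, the list median (orange bar) and the range holding 95% of medians of random lists matched on expression (grey band). The naive list has the highest median (2.61) and the neuroectoderm list the lowest (-1.84).

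The genes with the largest ratios by the fixed rule were led by DNMT3L (chromosome 21, 44246339 to 44262216 on GRCh38). PUS7L, a pseudouridine synthase gene (chromosome 12, 43718993 to 43758817), was at 0.0377 and 62.2 CPM, the linker histone gene H1-1 at 0.980 and 108 CPM, and the nuclear paraspeckle RNA NEAT1 (chromosome 11, 65422774 to 65445540) at 3.68 and 217 CPM. CR1L was at 0.0301 and 45.5 CPM. ERVH48-1, the suppressyn gene from an endogenous retrovirus (chromosome 21, 42916803 to 42925646), was at 9.18 and 441 CPM, and the long non-coding RNA PCAT14 (chromosome 22, 23536881 to 23547797) at 2.17 and 134 CPM. HPGD, the prostaglandin-degrading dehydrogenase gene, was at 8.82 and 235 CPM. FGF4, the protocadherin gene PCDHB5 (4.54), SOX15 (4.37) and GBX2-AS1 (4.18) completed the 12. GBX2-AS1 runs antisense to a coding gene, and whether strand was used in counting was not given. All 12 were higher within sets 1 and 3 as well, each with a log2 ratio of at least 2.02.

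The lowest ratio was that of MX2, an interferon-inducible GTPase gene (chromosome 21, 41361943 to 41409390), at 115 CPM in ESCs and 0.219 CPM in ffEPSCs (-6.58), with all 25 ffEPSC cells below every ESC cell. The non-coding gene D21S2088E (chromosome 21, 23361104 to 23384861) was at 148 and 1.27 CPM, the tetraspanin-like gene TM4SF18 (chromosome 3, 149318498 to 149334414) at 56.9 and 0.0321 CPM, and LIPA, the lysosomal acid lipase gene, at 110 and 2.51 CPM. RAB17 (-4.97), FABP7, the nuclear envelope gene SYNE4 (-4.90), LINC02335 (-4.82), SORBS2 (-4.59), S100A4, the cation channel gene TRPC4 (-4.44) and the muscle calcium-release gene TRDN (-4.14) followed. Within sets 1 and 3 all 12 were lower, with log2 ratios of -2.96 or below.

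Repeat counts came to 48.6 per 100 gene counts in ESCs and 47.9 in ffEPSCs. The row of the small subunit rRNA took 51.2% and 44.1% of them, and the 395 transposable element and satellite names with at least 100 repeat CPM in the higher library had a median log2 ratio of 0.18, with 5% below -0.29 and 5% above 0.78. The youngest HERVK elements stood apart. LTR5-Hs, the long terminal repeat of that family, was at 287 repeat CPM in ESCs and 10430.0 in ffEPSCs, 36.3-fold (95% interval 36.0 to 36.7), and its internal part HERVK-int at 761 and 12977 repeat CPM, 17.1-fold (16.9 to 17.2). Each of the 25 ffEPSC cells was above all 16 ESC cells for both, and log2 ratios were 5.15 and 4.26 within set 1 and 4.53 and 3.54 within set 3. SVA-F, the youngest subfamily of a composite retrotransposon, was at 111 and 1258 repeat CPM (3.49), whereas the other 5 SVA subfamilies had log2 ratios from 0.38 (SVA-D) to 0.88 (SVA-C), and the median of the 4 measured SVA names was 0.67 (1.0995 within set 1, 0.84 within set 3). SVA-F and LTR5-Hs were lowest in the same ffEPSC cell (389 and 2881 repeat CPM). Whether reads were shared between these 2 rows was not tested, so they may not be separate increases. HERVH48-int (4.77), MER48 (2.496), MER11A (1.71, but -0.12 within set 3) and HERV17-int (1.64) were also higher. HERVH48-int and the gene ERVH48-1 reported above each had 24 of 25 ffEPSC cells above all ESC cells. Whether the same reads gave both, and whether MER48 rose apart from them, was not tested, so these may not be separate increases.

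HERVH elements, abundant in human ESCs, differed little: HERVH-int was at 42896 and 46099 repeat CPM (0.10) and its repeat LTR7 at 9725 and 9690 (-0.01). LTR7Y was at 0.60 and the young LINE-1 subfamily L1HS at 0.53. L1HS was at 1.21 within set 3. The 8 young L1 names had a median of 0.31 (0.85 within set 1, 0.83 within set 3), the 19 Alu names 0.17 (0.52 and 0.22), the 4 HERVH and LTR7 names 0.12 (0.00 and -0.01), the 5 HERVL and MLT2 names -0.08 (0.75 and -0.16), the 5 HERVK and LTR5 names 1.44 (1.68 and 1.03) and the 14 other early embryo long terminal repeats 0.17 (0.52 and 0.34). The 3 measured satellite names had a median of 2.52, but 0.78 within set 1 and 1.16 within set 3. That median is the row (GAATG)n, with 64.3% of its ffEPSC counts in 1 cell and a log2 ratio of 1.14 without it. HSATII was at 21.7 and 164 repeat CPM, with 52.6% of its ffEPSC counts in 1 cell, and its log2 ratio of 2.86 was 1.87 without that cell. This was cell G5 of set 4, whose ffEPSC identity is examined below. SAR, a satellite outside that list, was at 2.60, with 24.5% of its ffEPSC counts and 66.4% of its ESC counts in 1 cell each, and leaving out single cells gave 2.28 to 3.92. Lower names differed less: LTR37-int (-1.04, but -0.29 within set 1), LTR21A (-1.003), the DNA transposon Charlie6 (-0.91), MER57B2 (-0.65), LTR25 (-0.47, but 0.29 within set 1), MER4B-int (-0.46, but 0.24 within set 1), HSMAR1 (-0.45, but 0.21 within set 3) and LTR3 (-0.42).

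**Figure D3:**
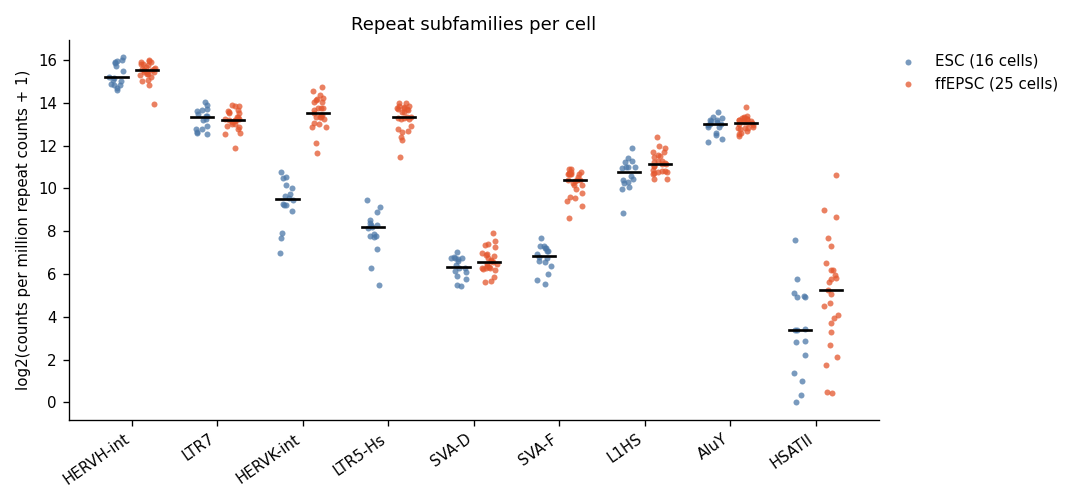
Levels per cell, as log2(repeat CPM + 1), of 9 repeat subfamilies in 16 ESC cells (blue) and 25 ffEPSC cells (orange), with black bars at the median over cells. HERVH-int and LTR7 overlap between the states, HERVK-int, LTR5-Hs and SVA-F lie higher in each ffEPSC cell, and HSATII is high in few cells.

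The median Spearman correlation between cells was 0.806 in ESCs and 0.794 in ffEPSCs, and the lowest of any pair 0.657 and 0.726, after thinning to 13000000 counts per cell. Thinning left out 2 cells of each state, and the 2 ESC cells were among the 4 low in POU5F1. A median of 13032 genes had a read per thinned ESC cell and 12787 per thinned ffEPSC cell (12870 and 12676 without thinning).

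Genes of 5 chromosomes were higher as a whole in the ffEPSC library, a split looked at only after the data were seen. The median log2 ratio was 0.31 on chromosome 5, 0.34 on chromosome 11, 0.33 on chromosome 14, 0.39 on chromosome 20 and 0.48 on chromosome 22, while the other 17 autosomes lay between -0.13 and 0.09. On these 5 chromosomes 75.8% of genes were higher, against 47.2% on the other autosomes. The medians of the 5 chromosomes were 0.31 to 0.41 within set 1 and -0.09 to 0.18 within set 3, so the shift did not hold in set 3, whose 2 ffEPSC cells were both among the 7 lower ones. Without the 4 ESC cells low in POU5F1 the 5 medians were 0.31 to 0.38. Per cell, 18 of 25 ffEPSC cells had a mean shift over the 5 chromosomes of 0.49 to 0.65 relative to ESC cells, 7 had -0.004 to 0.24, and ESC cells had -0.27 to 0.13. Many genes named above as higher lie on these chromosomes. They include FGF4, NEAT1, NDUFV1, SDHD, CCND1, IFITM1, IFITM2, IFITM3, PHLDA2 and KCNQ1OT1 on chromosome 11. PCDHB5, TCF7, STC2, PLK2, IL6ST and SPARC lie on chromosome 5, and DNMT3B, TFAP2C, ID1 and LAMA5 on chromosome 20. BMP4 and FOS lie on chromosome 14, and PCAT14, ZNRF3 and MORC2 on chromosome 22.

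**Figure D4:**
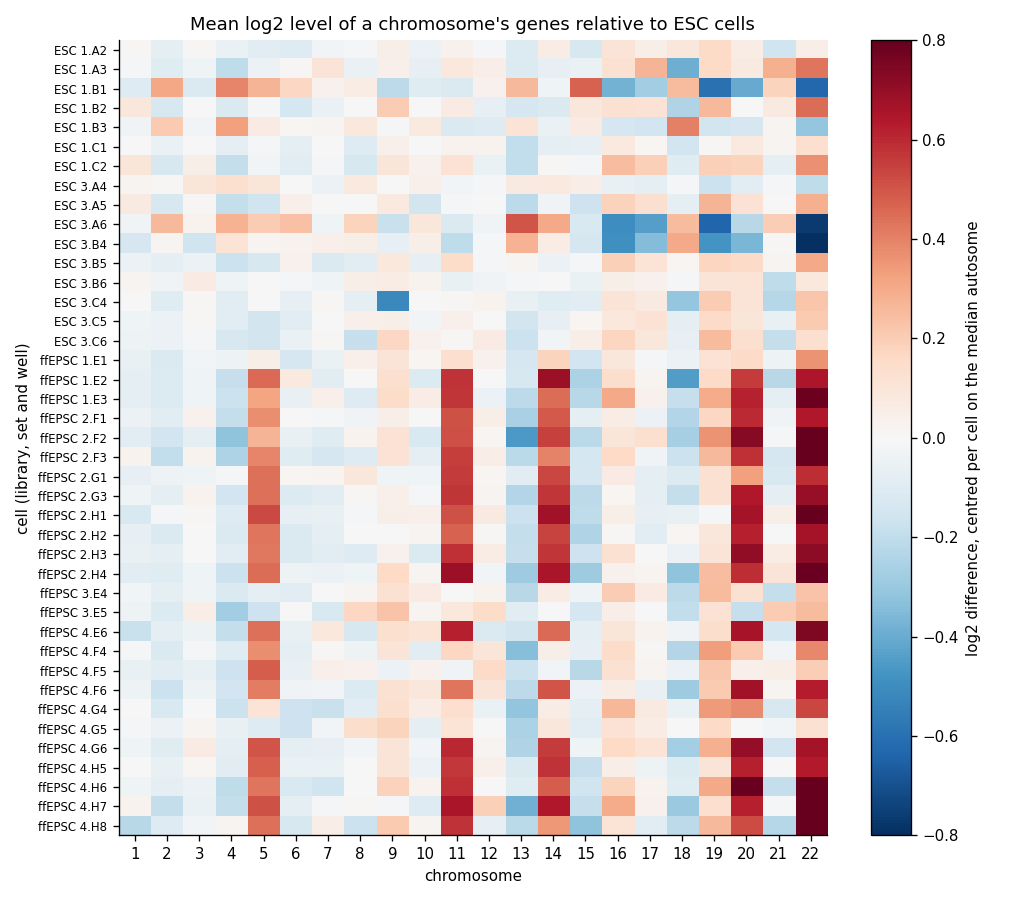
Mean log2 level of the genes of each autosome (columns) in each cell (rows: library, set and well) relative to the ESC cells, centred per cell on the median autosome. Chromosomes 5, 11, 14, 20 and 22 are higher together in 18 of 25 ffEPSC cells, and part of them in some of the other 7, such as chromosome 5 in cell F5 of set 4.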

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

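All tests below were chosen after the results were seen.

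Repeat rows that are neither transposable elements nor listed satellites were not part of the comparisons, and 4 of them stood out. Per repeat count, the composite row COMP-subunit-ACRO-rnd-5-family-38 had a log2 ratio of 2.81 of the ffEPSC over the ESC library, with 14 of 25 ffEPSC cells above all ESC cells. The simple repeat (GAGTG)n had 2.19, with 21 of 25 cells above all ESC cells. For (GGAAT)n the log2 ratio was 2.70, and a single cell held 66.8% of the ffEPSC counts, without which it was 1.21. For (ATTCC)n it was 2.48, with 68.3% of the ffEPSC counts in a single cell, and 0.91 without it. The unit GGAAT is that of the listed satellite row (GAATG)n begun at another base, and ATTCC is its reverse complement. Both rows thus repeat a unit reported above, where most ffEPSC counts also lay in 1 cell, and are not separate signals.

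Genes of chromosomes 5, 11, 14, 20 and 22 were higher together in 18 of 25 ffEPSC cells. A few strong genes as its source are argued against, since at least 73.2% of the genes on each of the 5 chromosomes were higher. Amplification that differs with gene density is argued against as the whole source, since the highest median among the gene-dense chromosomes 16, 17 and 19 was 0.09. However, chromosomes 20 and 22 were low along with them in the 4 ESC cells low in POU5F1. In cell B4 of set 3 they had -0.36 and -0.85, beside -0.49, -0.35 and -0.48. Without those 4 cells the medians were 0.31 on chromosome 20 and 0.36 on chromosome 22, so a part in their shift is not excluded. The set of cells is argued against as the whole source by set 4, where 4 ffEPSC cells below the threshold stood beside 7 above it. However, 3 of the 4 were high on some of the 5 chromosomes. These were cells F4 (0.37) and F5 (0.49) on chromosome 5 and cell G4 on chromosomes 20 (0.38) and 22 (0.54). Cell G4 was high on the gene-dense chromosomes 19 (0.34) and 16 (0.27) too, so its pattern need not be a part of the shift. The median shift of the 18 cells, 0.58, is close to the log2 ratio of 3 copies over 2, 0.58. Their medians were 0.57 on chromosome 11, 0.54 on chromosome 14 and 0.62 on chromosome 20. Those on chromosome 5 (0.44) and chromosome 22 (0.73) lay further away, and ESC cells themselves had a median of 0.13 on chromosome 22. Extra copies of these chromosomes in most ffEPSC cells may be a candidate explanation, with a less close match for chromosomes 5 and 22. DNA was not measured, so this stays a hypothesis found and tested on the same data.

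The 5 ffEPSC cells with little or no shift, of which G4 of set 4 (mean 0.24) and E1 of set 1 (0.17) lay above the highest ESC cell (0.13), could be ESCs, or hold RNA of ESCs, and their ffEPSC identity was therefore examined. For the 14 genes read in ESCs and nearly absent from the other ffEPSC cells, the summed level in these cells was 0.397% to 10.9% of the ESC level. In single ESC cells it was 77.8% to 129%. HERVK-int stood at 3197 to 18205 CPM of repeat counts, above the highest ESC cell at 1722. Both argue against whole ESCs in these wells. However, the mean log2 level of 8 naive genes off the 5 chromosomes was within the ESC range (median 0.40, highest 1.93) in cells G4 (1.51) and G5 (0.53) of set 4. The lowest of the other ffEPSC cells, at 1.12, was in that range as well, so in this mean only G5 lay below the other ffEPSC cells. LTR5-Hs, however, was below the lowest of those (6599 repeat CPM) in E4 (6427) and E5 (5385) of set 3, and in G4 (4935) and G5 (2881). In E1 (9987) it was not. HERVK-int was below their lowest (7554 repeat CPM) only in G4 (4426) and G5 (3197), and DNMT3L below theirs (26.45 CPM) only in E4 (1.80) and G5 (14.2). The highest value, 10.9%, was in G5, but the median over the 14 genes was 0.197% there, and MX2, at 31.1 CPM or more in each ESC cell, had 0 reads (at most 0.202 CPM), so an ESC share of RNA of that size is argued against as well. G5 was also the lowest ffEPSC cell in POU5F1 (518 CPM) and HERVH-int (15963 repeat CPM), and the highest in HSATII (1571 repeat CPM). Why naive genes and ERVH48-1 (1.75 CPM) of G5 lay in the ESC range, and whether the 5 cells differ from the rest in how far conversion went, was not tested.

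HERVK-int and LTR5-Hs were higher in the ffEPSC library. A smaller rRNA share of repeat counts in ffEPSCs is argued against as the whole source, since the HERVK-int log2 ratio per gene count was 4.07. So are a few cells, since 25 of 25 ffEPSC cells were above all ESC cells, the set, since the lower of the ratios within sets 1 and 3 was 3.54, and the chromosome shift, since the ratio in the 5 ffEPSC cells with little or no shift was 3.48. How reads that map to many copies were assigned was not given and stays open, as does the library itself, with 1 sample per state. A difference in activity of these elements between the states may be a candidate explanation and is untested.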

How the results depend on the processing

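Single sets, cells left out in turn, 4 ESC cells low in POU5F1 left out, the 5 ffEPSC cells with little or no chromosome shift and genes of the 5 chromosomes left out were chosen after the data were seen; the other settings were chosen before. With 1 sample per state, a value counted as moved when it left its counting interval, which is narrow at this depth. Leaving out mitochondrial genes or changing the cell filter removed nothing and tests nothing, and shares per repeat class, such as LINE or LTR, were not computed, since the tables name no class. Of 97 named genes at 2-fold or more, 95 stayed there in the same direction with the mean of cells and 95 with TMM, 97 with a pseudocount of 0.1, 78 within set 1, 71 within set 3, 88 without ESC cells low in POU5F1 and 76 in ffEPSC cells with little or no shift. Of 8 list medians at 2-fold or more, 3 stayed there with no CPM floor, 6 within set 1, 5 within set 3, 4 in cells with little or no shift and 6 without genes of the 5 chromosomes. Of 10 repeats, 8 stayed within set 1, within set 3 and in cells with little or no shift. All 274 shares of cells with reads stayed in their interval at other thinning depths. These intervals are wide with so few cells, and shares moved by up to 21.2 points, so this tests little.

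The core pluripotency median was 0.45 with the mean of cells, 0.36 with TMM, 0.38 with no CPM floor, 0.60 within set 1, 0.49 within set 3, 0.24 without the 4 ESC cells, 0.46 in cells with little or no shift, and 0.35 to 0.46 with each cell left out. The naive median was 3.06 with a pseudocount of 0.1, 4.69 at 20 CPM or more, 1.76 with no floor, 3.45 within set 1, 2.25 within set 3, 2.399 without the 4 ESC cells (the KLF4 log2 ratio), 2.06 in cells with little or no shift, 2.48 without the 5 chromosomes, and 2.43 to 2.95 with each cell left out. The primed median was -0.82 with TMM, -0.27 within set 1, -0.47 in cells with little or no shift, and -0.82 to -0.74 with each cell left out. Pearson r across genes was 0.907 with the mean of cells, 0.879 with a pseudocount of 0.1, 0.882 at 20 CPM, 0.963 with no floor, 0.830 within set 1, 0.835 within set 3, 0.906 without the 4 ESC cells and 0.899 in cells with little or no shift.

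LTR5-Hs was at 5.15 per gene count, 5.16 with the mean of cells, 4.94 with simple repeats and RNA genes out of the total, 5.15 within set 1, 4.53 within set 3, 4.36 in cells with little or no shift, 5.28 without the 4 ESC cells and 5.09 to 5.30 with each cell left out. HERVK-int was at 4.07, 4.05, 3.85, 4.26, 3.54, 3.48, 4.32 and 3.98 to 4.198 under the same settings in that order, and HERVH-int at 0.083, 0.092, -0.14, 0.0079, 0.046, -0.35, 0.0015 and 0.054 to 0.16, so its direction was not stable.

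Among lists, and genes and repeats named by the fixed rule, with a log2 ratio of at least 1 in size, within set 1 the direction was lost or turned for TBXT (-0.64), LINC01356 (-0.60), CCNA1 (0), KRT7 (1.19), MORC2 (-0.20), IL6ST (-0.12) and ZNF597 (-0.22). Within set 3 it was for the 8-cell list (-0.50), TBXT (-0.019), ALPG (0), CCNA1 (-1.43), DUSP4 (-0.37), PIM1 (-0.39), IL6ST (-3.14), JUN (-0.27), ZNF597 (-0.46) and MER11A (-0.12). In ffEPSC cells with little or no shift it was for LINC01356 (-0.82), PIM1 (-0.043) and ZNF597 (-0.39), and without genes of the 5 chromosomes for the mesoderm and definitive endoderm list (-0.42). Genes named outside the rule turned as well: ZNRF3 (-1.07) and DPPA5 (-1.54) within set 1, and DPPA2 (-0.45), DPPA5 (-1.42) and SPARC (-0.54) within set 3. Smaller values also turned, among them the amnion list (-0.31 within set 1, -2.66 within set 3), the DNA methylation list (0.18 within set 1, 0.33 within set 3, 0.19 in cells with little or no shift), the p53 list (-0.08 and -0.34 within sets 1 and 3), LTR25 (0.29) and MER4B-int (0.24) within set 1, HSMAR1 (0.21) within set 3, the imprinted list without the 5 chromosomes (-0.18), the pluripotency lncRNA list at 20 CPM, with no floor and without the 5 chromosomes (0.19), and POU5F1 without the 4 ESC cells (-0.017). The cause was not tested.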
